A study of Mus musculus with 12 samples.

How the data were processed

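Single-cell RNA was measured with 10x single cell 3' v3.1 chemistry in paraspinal tumors of mice, as 12 libraries in 4 groups: untreated (2), vehicle (3), MEK inhibitor at 1.5 mg/kg per day (4) and SHP2 inhibitor at 10 mg/kg per day (3), over 30 days. Per the labels' protocols, the mice were perfused, tumors were minced and digested with collagenase and Dispase, and viable cells were loaded, so cells that did not survive digestion were not seen. The labels give each sample its treatment and do not say whether any 2 samples came from 1 mouse, so p-values measure the spread between these samples. Titles of vehicle samples carry 2 kinds of prefix whose meaning the labels do not give, and both were treated as vehicle. No 2 libraries of a group held the same counts (lowest chi-square per degree of freedom 29.6). The sex of the mice, read from Xist and Ddx3y, was mixed within the vehicle, MEK inhibitor and SHP2 inhibitor groups, and both untreated mice were female. MEK inhibitor library 3 held Xist at 14.4 CPM beside Ddx3y at 95.4 CPM.

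Deposited values are, per the file headers, whole UMI counts per gene and barcode without normalization. The submitters name Cell Ranger 2.1.1 on build mm10 and the matrix headers software version 3.1.0, so the version is open. Each library listed 27998 genes by symbol and Ensembl identifier. Chromosome, start and end (from 1) came from the GENCODE annotation of that build. Counting by 3' tag can mix genes that overlap or near-identical copies. Barcodes had been selected before deposit. The lowest UMI count was 500 in untreated libraries 1 and 2, vehicle 1 and 2 and MEK inhibitor 1. It was 567 to 847 in vehicle 3 and the other drug libraries, so drug and selection partly overlap.

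Barcodes were kept with at least 300 genes, at least 500 UMIs and under 20% mitochondrial UMIs. In each library those with the highest scrublet scores were removed as likely doublets. The percent removed grew in proportion to the number of barcodes, from 2.73 to 7.71% of a library, which took 3832 barcodes and left 64013 cells. Cells of all libraries were clustered together with scanpy 1.11.5 (counts scaled to 10000 per cell and logged, 2000 variable genes, 30 principal components, 15 neighbors, Leiden resolution 1.0 as run by igraph 0.11.9), without integration of libraries. A mixed immune cluster was split again at 0.5. Names come from marker lists fixed before the data were examined. A cluster stayed unnamed with under 3 markers detected, with leading genes of another type, with over 90% of its cells from 1 library, or with a low UMI count and no marker among its top 10 genes. Sub-clusters led by genes of types outside the lists were also left unnamed, by a rule set after the data were seen, and count in the unnamed share. Among top 10 genes, fibroblast-like clusters 9 and 10 and Schwann-like clusters 5 and 13 held 0 markers of their class.

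Shares are percent of kept cells per library, compared by a two-sided exact permutation test of the difference of means with Benjamini-Hochberg adjustment over 14 classes. With 4 against 3 libraries the smallest p is 0.0286 (1 of 35 splits), with 3 against 3 it is 0.1, and against the 5 drug-free libraries it is 0.00794 and 0.0179. The drug-free libraries mix untreated and vehicle mice.

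For genes, cells were not treated as replicates. UMI counts were summed per library over each class with at least 20 cells (macrophage-like 166 to 3430 cells and 1247391 to 18847995 UMIs a library, Schwann-like 479 to 3106 cells and 2396151 to 15176345 UMIs, fibroblast-like 283 to 1611 cells and 4998740 to 34081038 UMIs). The sums went through edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, quasi-likelihood F test, all 4 groups in one fit, Benjamini-Hochberg over all genes tested, called under 0.05). CPM values are edgeR's, per library, and ± is the SD between libraries for CPM and the standard error for a log2 fold change. A group at 0 was set against a floor of 3 counts. The same steps run on simulated counts for each comparison, with 200 genes changed, found 58% of 2-fold and 92% of 4-fold changes for macrophage-like cells with the MEK inhibitor (38% and 76% with the SHP2 inhibitor) among 9589 genes. They found 56% and 88% with either drug in Schwann-like cells among 12816 genes, and 60% and 86% (MEK inhibitor) and 48% and 84% (SHP2 inhibitor) in fibroblast-like cells among 12725 genes.

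Genes named in the text follow a rule fixed before the data were examined. In each class and drug comparison these are the 6 highest and 6 lowest log2 fold changes among genes called, with a mean CPM of at least 20 and with drug libraries all above or all below vehicle. Up to 4 members with the smallest p of each called list were added, with fixed genes of the drug targets, Nf1 and macrophage signals at a mean CPM of at least 5. Mitochondrial, ribosomal, hemoglobin, immunoglobulin, unnamed-model and sex-linked genes were left out. Not each gene that meets the rule is named. Ccnd1, Etv4, Phlda1, Spred1 and a few others are said to be chosen after their values were seen.

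The 21 pathway lists and 20 cell type marker lists were fixed before the data were examined. Counts of a list are over its members measured in a class, and its median is of log2 fold changes. Lists were tested with camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over lists within a class and comparison, and again with an estimated correlation and with fry. With an estimated correlation 0 lists were called in any of the 12 comparisons. For each gene the level in a class was divided by its level in the whole library. Genes under 30% of that level were counted apart, since free RNA of other cells reaches every droplet. Marker lists of other cell types were read the same way, and are given beside the pathway lists.

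Alternatives, with effects given in the closing section, were DESeq2 1.42.0, RLE size factors, no low-count filter, only the 2 groups of a comparison in the fit, untreated and vehicle pooled, doublets kept, a stricter cell filter (500 genes), sums thinned to equal totals, another Leiden resolution, edgeR on cell counts, and each library left out in turn. Those added after the data were seen were sex as a covariate, genes at 30% or more of the whole-library level, low-UMI clusters left out, another denominator for shares, 1 cluster of each class, cluster 9 of fibroblast-like cells, and macrophage markers in fibroblast-like cells thinned to 5000 UMIs. Overlap between the drugs was set against 20 simulated draws of unchanged groups sharing the vehicle libraries and 5 with separate controls. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9. CX3CR1 inhibition, named in the series title, was not analysed here.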

Results

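RNA of single cells was measured with a 10x droplet assay that tags the 3' ends of transcripts, in paraspinal tumors of mice in which Cre under the Dhh promoter deletes Nf1 in the Schwann cell lineage. Such mice are a model of plexiform neurofibroma, a nerve tumor in which Schwann cells lacking Nf1 grow among fibroblasts and macrophages. The 12 libraries fell into 4 groups. Of these, 2 libraries came from untreated mice, 3 from mice given vehicle, 4 from mice given a MEK inhibitor named PD-032590 at 1.5 mg/kg per day, and 3 from mice given the SHP2 inhibitor RMC-4550 at 10 mg/kg per day, with treatment lasting 30 days. SHP2, the protein of Ptpn11, passes signals of receptor tyrosine kinases to RAS, which Nf1 switches off, and MEK lies further down the same pathway. The libraries held 77582 barcodes, from 3386 to 9627 each, of which 64013 were kept as cells. Totals ran from 17229055 UMIs in untreated library 1 to 73587516 in untreated library 2. The median kept cell had 3136 and 8873 UMIs in the untreated libraries, 5954 to 6806 with vehicle, 3600 to 4920 with the MEK inhibitor and 3592 to 4137 with the SHP2 inhibitor, so the drug libraries were shallower per cell than the vehicle libraries.

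Nf1 (ENSMUSG00000020716, chromosome 11, 79339693 to 79581612, mm10) was measured at 46.2 to 75.6 CPM (counts scaled by library size) across libraries in Schwann-like cells and at 29.6 to 50.8 in fibroblast-like cells. All groups carry the same allele, and 3' tags outside the deleted part check nothing about the deletion. Ptpn11 (ENSMUSG00000043733, chromosome 5, 121130533 to 121191397) fell in fibroblast-like cells with the SHP2 inhibitor (50.9 ± 3.3 against 69.5 ± 0.968 CPM, log2 fold change -0.45 ± 0.12, adjusted p = 0.021, SD and SE, n = 3 and 3, edgeR). That call was lost without vehicle library 1 (-0.44), vehicle library 2 (-0.45), SHP2 inhibitor library 1 (-0.42) or SHP2 inhibitor library 2 (-0.42). Map2k2 (ENSMUSG00000035027, chromosome 10, 81105915 to 81133975), which encodes a MEK kinase, fell in the same cells with the SHP2 inhibitor (56.3 ± 0.968 against 86.1 ± 3.56 CPM, log2 fold change -0.61 ± 0.12, adjusted p = 0.0064) and with the MEK inhibitor (-0.47 ± 0.11, adjusted p = 0.013; not called without vehicle library 2, -0.44).

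The first comparison asked which cells the tumors held after each drug. Macrophage-like cells made up 32.6% ± 12.2 (SD, n = 3) of kept cells with vehicle and 25.0% ± 6.56 (n = 2) in untreated tumors, against 5.33% ± 2.68 (n = 4) with the MEK inhibitor and 4.01% ± 1.12 (n = 3) with the SHP2 inhibitor. Dendritic-like cells were at 7.37% ± 1.38 with vehicle, 0.962% ± 1.01 with the MEK inhibitor (2.38% in library 1, 0.196 to 1.00% in the others) and 0.762% ± 0.537 with the SHP2 inhibitor, and T-like cells at 1.21% ± 0.534, 0.238% ± 0.185 and 0.257% ± 0.0791. Schwann-like cells made up 14.9% ± 5.66 with vehicle, 38.6% ± 5.05 with the MEK inhibitor and 33.7% ± 5.82 with the SHP2 inhibitor. Fibroblast-like cells were at 15.3% ± 5.58 with vehicle, 14.9% ± 7.85 and 14.2% ± 3.77 with the drugs. Neutrophil-like cells were at 0.0720% ± 0.0186, 0.622% ± 0.285 and 0.126% ± 0.178 (0.330% in SHP2 inhibitor library 2, 0.0475 and 0% in the other two).

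Cell types of the sensory ganglion took other shares as well. Neuron-like cells were at 4.53% ± 4.94 (SD, n = 3) with vehicle (10.2% in vehicle library 3, 1.72 and 1.64% in the other two), 20.1% ± 12 (n = 4) with the MEK inhibitor and 28.9% ± 5.04 (n = 3) with the SHP2 inhibitor. Most were barcodes of few UMIs: cluster 12 (median 793) held 43.6% of them with vehicle, 72.3% with the MEK inhibitor and 78.4% with the SHP2 inhibitor, and cluster 7 (median 1195) 45.4, 21.3 and 17.3%. With low-UMI clusters left out, the differences from vehicle went from 15.6 and 24.4 to 1.28 and 1.19 percentage points. Satellite glial-like cells, which wrap those neurons, were at 1.08% ± 1.52 (2.83% in vehicle library 3, 0.229 and 0.185% in the other two), 4.45% ± 1.90 and 4.16% ± 0.263. Barcodes in clusters left without a name were 18.2% with vehicle, 6.64% with the MEK inhibitor and 5.34% with the SHP2 inhibitor. Relative to fibroblast-like cells, macrophage-like cells numbered 182 ± 55.3 (SD, n = 5) per 100 in the drug-free libraries, untreated and vehicle together, 36.0 ± 1.44 (n = 4) with the MEK inhibitor and 28.3 ± 4.07 (n = 3) with the SHP2 inhibitor.

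In the two-sided exact permutation test against vehicle, the macrophage-like, dendritic-like, T-like, Schwann-like and neutrophil-like shares with the MEK inhibitor gave the smallest p that 35 splits allow, p = 0.0286 (adjusted p = 0.08 over 14 classes). Against the 5 drug-free libraries the same 5 classes passed the exact test (p = 0.00794, adjusted p = 0.0222), and so did the mural-like and satellite glial-like shares (p = 0.0238, adjusted p = 0.0476). With fewer splits once a library was left out, the macrophage-like call was lost without any 1 of the 9 libraries (differences of -26.8 to -20.8 percentage points, against -24.3), and the Schwann-like, T-like, dendritic-like and satellite glial-like calls were lost without any 1 of them except MEK inhibitor library 1. No share can pass for the SHP2 inhibitor against vehicle, since the smallest exact p is 0.1 (adjusted p = 0.2). Against the drug-free libraries the smallest exact p was 0.0179 (adjusted p = 0.05) for Schwann-like, T-like, dendritic-like, neuron-like and satellite glial-like cells, and p = 0.0357 (adjusted p = 0.0625) for macrophage-like cells. An edgeR test on cell counts, run as an alternative, gave log2 fold changes against vehicle of -2.62 (adjusted p = 0.0029) and -3.02 (adjusted p = 0.0024) for macrophage-like cells with the MEK and SHP2 inhibitors, and 1.37 (adjusted p = 0.039) for Schwann-like cells with the MEK inhibitor (1.18, adjusted p = 0.083, with the SHP2 inhibitor). Between the drugs no share passed the exact test (smallest adjusted p = 0.8), and neutrophil-like cells had p = 0.0571.

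**Figure D1:**
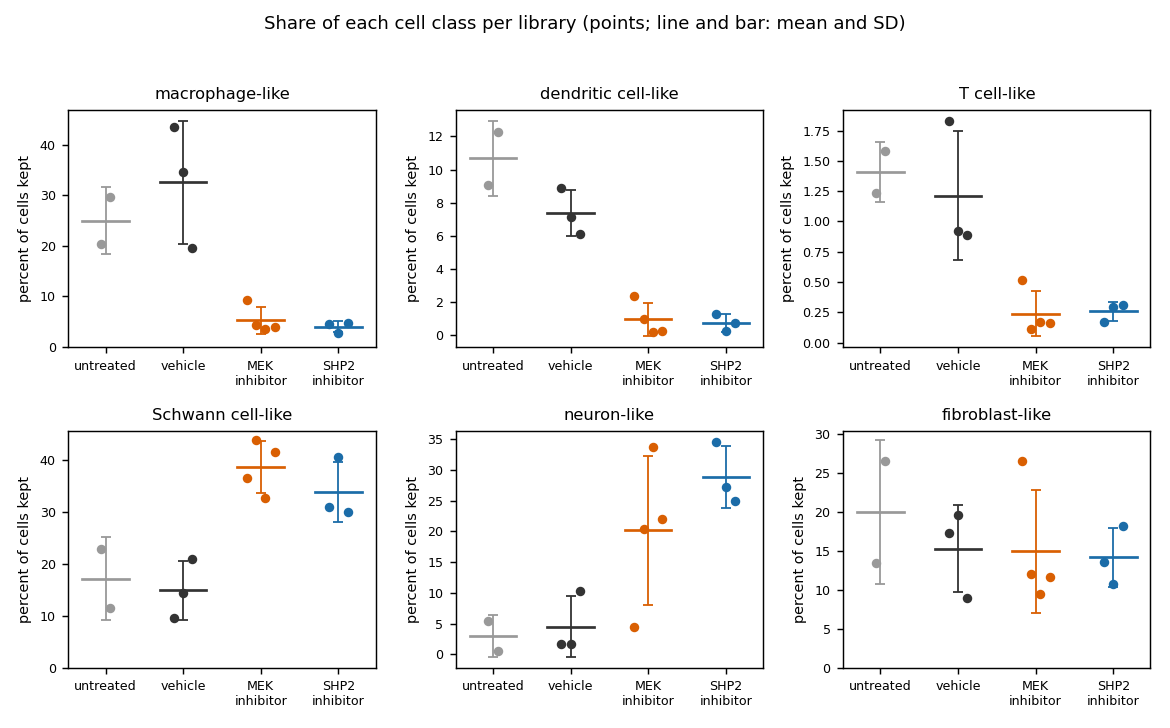
Percent of kept cells in each class (y axis, linear) per library (points) in the 4 groups, with a line and bar for the mean and SD. Macrophage-like cells sat at 3.61 to 9.32% in the 4 MEK inhibitor libraries, against a vehicle mean of 32.6%.

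Vehicle was compared with no treatment to ask whether dosing itself moved genes. No gene passed edgeR's test in macrophage-like, Schwann-like or fibroblast-like cells (0 of 10116, 13072 and 13056 tested). At an unadjusted p under 0.05 there were 419, 624 and 572 genes, and DESeq2 called 0, 1 and 5. Without untreated library 1, edgeR called 1 gene in macrophage-like cells. Cell cycle genes were lower with vehicle in macrophage-like cells (median -0.42, adjusted p = 0.00014, adjusted p = 0.25 with an estimated correlation) and higher in fibroblast-like cells (median 0.58, adjusted p = 0.021, adjusted p = 0.81 with an estimated correlation), with 0 members past the test in either. Of the 21 pathway lists camera called 4 in macrophage-like, 6 in Schwann-like and 1 in fibroblast-like cells, and 0 with an estimated correlation. Neuron markers were higher with vehicle in all 3 classes, with median log2 fold changes of 1.28, 1.46 and 1.25 (adjusted p = 9.3e-08, 0.00073 and 5.5e-05, and adjusted p = 0.66, 0.49 and 0.84 with an estimated correlation).

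The effect of the MEK inhibitor on macrophage-like cells was tested next. Ccl3, a chemokine that draws leukocytes, rose (2314 ± 968 against 463 ± 147 CPM, log2 fold change 2.32 ± 0.32, adjusted p = 0.00087, SD and SE, n = 4 and 3), as did the cytokine Tnf (635 ± 249 against 207 ± 51.1 CPM, log2 fold change 1.62 ± 0.29, adjusted p = 0.003). The scavenger receptor Cd163 rose (171 ± 95.6 against 15.3 ± 6.49 CPM, log2 fold change 3.52 ± 0.50, adjusted p = 0.00096), and so did the collagenase Mmp13 (114 ± 36.7 against 6.73 ± 0.825 CPM, log2 fold change 4.10 ± 0.34, adjusted p = 4.8e-05). The Fc receptor gene Fcgr4 fell (29.2 ± 18.9 against 340.1 ± 8.25 CPM, log2 fold change -3.54 ± 0.47, adjusted p = 0.00077), together with Ly6a (-3.86 ± 0.54), the interleukin receptor gene Il2ra (-3.47 ± 0.57) and Stat4 (-3.08 ± 0.45). Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879), the receptor named in the title of the series, fell from 291 ± 41.2 to 182 ± 23.9 CPM (-0.67 ± 0.14, adjusted p = 0.0089). The growth factor receptor Csf1r did not pass (0.19 ± 0.14, adjusted p = 0.4). Lyve1 (3.66 ± 1.06), among the 6 highest, was not called without vehicle library 1 (3.06), 2 (4.18) or 3 (3.86) or MEK inhibitor library 1 (2.55) or 4 (3.73), and Ccl24 (3.32 ± 0.73) not without vehicle library 1 (3.11).

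Of inflammatory cytokines and chemokines 10 of 18 rose and 1 fell (11 and 1 adjusted over the list alone), including Ccl4 (2.03 ± 0.33) and Ccl2 (2.53 ± 0.43). The inflammatory list median was 1.21 (adjusted p = 9.5e-05, adjusted p = 0.28 with an estimated correlation). Of genes that mark resident-like macrophages, 9 of 13 rose and 0 fell (11 and 0 adjusted over the list alone), among them Pf4, Folr2 and Cbr2 at 1.93 ± 0.29, 2.36 ± 0.45 and 3.13 ± 0.46. The resident-like list median was 2.36 (adjusted p = 3e-06, adjusted p = 0.28 with an estimated correlation). In the lipid-associated list 7 of 14 rose and 0 fell (9 and 0 adjusted over the list alone), with Cd36 at 1.80 ± 0.28 and Cd9 at 1.81 ± 0.32. The lipid-associated list median was 1.05 (adjusted p = 0.00087, adjusted p = 0.28 with an estimated correlation). Receptor tyrosine kinase ligands moved up as a list: 9 of 13 rose and 1 fell (9 and 2 adjusted over the list alone), with Pdgfc at 2.82 ± 0.48 and Igf1 at 1.44 ± 0.23. The ligand list median was 0.98 (adjusted p = 0.0037, adjusted p = 0.23 with an estimated correlation). For the receptors themselves, 3 of 8 rose and 0 fell (4 and 0 adjusted over the list alone), with Igf1r at 1.27 ± 0.18. The receptor list median was 1.00 (adjusted p = 0.0042, adjusted p = 0.23 with an estimated correlation). Of MHC class I genes, which present peptides to T cells, 0 of 10 rose and 6 fell (1 and 8 adjusted over the list alone), with H2-T23 at -1.11 ± 0.20. The MHC class I list median was -0.57 (adjusted p = 0.0017, adjusted p = 0.28 with an estimated correlation). For MHC class II, 1 of 9 rose and 2 fell (1 and 6 adjusted over the list alone). Their median was -0.71 (adjusted p = 0.022, adjusted p = 0.54 with an estimated correlation). Of collagen and matrix genes 0 of 18 rose and 4 fell (0 and 6 adjusted over the list alone), with Thbs1 at -2.86 ± 0.51. The matrix list median was -0.76 (adjusted p = 0.00014, adjusted p = 0.35 with an estimated correlation). Of myelin genes 6 of 13 rose and 0 fell (10 and 0 adjusted over the list alone), with Pmp22 at 1.46 ± 0.18 and Drp2 at 2.12 ± 0.34. The myelin list median was 1.46 (adjusted p = 0.00054, adjusted p = 0.28 with an estimated correlation). Of Schwann cell markers read in the same macrophage-like cells 4 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.99 (adjusted p = 0.013). Of neuron markers there 1 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 1.29 (adjusted p = 0.021). With an estimated correlation adjusted p was 0.54 or more.

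In all, edgeR called 1529 of 10116 genes in macrophage-like cells with the MEK inhibitor (910 up, 619 down), and 1298 of these lay at 30% or more of the whole-library level. The count was 506 without vehicle library 1, 652 without vehicle library 2 and 885 without MEK inhibitor library 4, and 87 within cluster 15. Different clusters held the class: cluster 11, led by Fcgr4 and C1qa, held 64.9% of it with vehicle and 12.9% with the MEK inhibitor, while cluster 15, led by Ccl3, Pf4 and Tnf, held 13.1% and 79.6%. In that cluster, a comparison chosen after the data were seen, the calls of the resident-like (median 0.44, 0 members past the test, adjusted p = 0.28), lipid-associated (0.23, adjusted p = 0.63), ligand (0.40, adjusted p = 0.69) and receptor lists (0.80, adjusted p = 0.075) were lost, and the inflammatory list had a median of 0.73 with 1 member up (adjusted p = 0.01, adjusted p = 0.71 with an estimated correlation). MHC class II genes were higher in that cluster (median 1.26, adjusted p = 0.00022, adjusted p = 0.41 with an estimated correlation).

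The SHP2 inhibitor was set against vehicle in the same cells. Ccl3 rose (3147 ± 433 against 463 ± 147 CPM, log2 fold change 2.77 ± 0.33, adjusted p = 0.00083, SD and SE, n = 3 and 3), with Tnf (776 ± 34.3 against 207 ± 51.1 CPM, log2 fold change 1.91 ± 0.30, adjusted p = 0.0023). The lipase gene Lpl rose (42.8 ± 7.76 against 3.51 ± 3.38 CPM, log2 fold change 3.66 ± 0.53, adjusted p = 0.0014), as did Cd163 (3.24 ± 0.51) and Mmp13 (3.07 ± 0.35). Fcgr4 fell (35.6 ± 28.7 against 340.1 ± 8.25 CPM, log2 fold change -3.28 ± 0.53, adjusted p = 0.0026), with Stat4 (-3.00 ± 0.51). Cx3cr1 fell to 135 ± 15 CPM (-1.11 ± 0.16, adjusted p = 0.0014). Cacna1a (4.62 ± 0.99) was not called without vehicle library 1 (4.67) or SHP2 inhibitor library 1 (3.11) or with pooled controls (2.07), Gpnmb (4.38 ± 1.03) not without vehicle library 1 (4.06), vehicle library 2 (3.95) or SHP2 inhibitor library 3 (3.45) or with pooled controls (2.84), and Fn1 (-3.45 ± 0.89) not without vehicle library 2 (-3.44) or SHP2 inhibitor library 1 (-3.37), 2 (-3.34) or 3 (-3.75).

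Of inflammatory cytokines and chemokines 10 of 18 rose and 0 fell (11 and 0 adjusted over the list alone). Their median was 1.14 (adjusted p = 8.7e-06, adjusted p = 0.24 with an estimated correlation). Of lipid-associated genes 8 of 14 rose and 0 fell (10 and 0 adjusted over the list alone), with Lgals3 at 2.07 ± 0.42. The lipid-associated list median was 1.03 (adjusted p = 2.9e-05, adjusted p = 0.24 with an estimated correlation). Of resident-like genes 4 of 13 rose and 0 fell (7 and 0 adjusted over the list alone), with Pf4 at 1.57 ± 0.30 and Cbr2 at 2.31 ± 0.47. The resident-like list median was 1.57 (adjusted p = 0.0035, adjusted p = 0.4 with an estimated correlation). Of receptor tyrosine kinase ligands 6 of 13 rose and 0 fell (7 and 2 adjusted over the list alone), with Pdgfa at 1.23 ± 0.17. The ligand list median was 1.23 (adjusted p = 0.0032, adjusted p = 0.24 with an estimated correlation). Of macrophage-attracting ligands 2 of 6 rose and 0 fell (3 and 0 adjusted over the list alone), with Ccl2 at 2.18 ± 0.44. The attractant list median was 1.05 (adjusted p = 0.014, adjusted p = 0.24 with an estimated correlation). Of cell cycle genes 0 of 14 rose and 3 fell (0 and 4 adjusted over the list alone). Their median was -0.42 (adjusted p = 0.031, adjusted p = 0.3 with an estimated correlation). Of collagen and matrix genes 0 of 18 rose and 6 fell (0 and 7 adjusted over the list alone). Their median was -1.02 (adjusted p = 0.00031, adjusted p = 0.38 with an estimated correlation). Of myelin genes 10 of 13 rose and 0 fell (10 and 0 adjusted over the list alone). Their median was 1.81 (adjusted p = 1.1e-05, adjusted p = 0.24 with an estimated correlation). For immature and repair Schwann cell genes, 3 of 10 rose and 1 fell (7 and 1 adjusted over the list alone). Their median was 1.40 (adjusted p = 0.028, adjusted p = 0.3 with an estimated correlation). Of Schwann cell markers 7 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 1.45 (adjusted p = 5.1e-05, adjusted p = 0.61 with an estimated correlation), and of neuron markers 0 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 1.26 (adjusted p = 0.0074, adjusted p = 0.61 with an estimated correlation).

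The SHP2 inhibitor comparison called 1268 genes in macrophage-like cells (728 up, 540 down), 1074 of them at 30% or more of the whole-library level. The count was 435 without vehicle library 1, 518 without vehicle library 2, 778, 490 and 515 without SHP2 inhibitor library 1, 2 and 3, and 88 within cluster 15. That cluster held 82.0% of the class with the SHP2 inhibitor and cluster 11 held 4.25%. Within it the resident-like list had a median of -0.22 (adjusted p = 0.38). The lipid-associated (0.066, adjusted p = 0.13), ligand (0.54) and attractant lists (0.56, adjusted p = 0.46 for both) also lost their calls there, and the inflammatory list had a median of 0.71 with 1 member up (adjusted p = 0.00092). MHC class II (median 1.63, adjusted p = 0.00014) and interferon genes (1.05, adjusted p = 0.0018) were higher there, and the Cx3cr1 list lower (-0.62, 2 members down, adjusted p = 0.00071). Adjusted p was 0.35 or more for these with an estimated correlation.

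**Figure D2:**
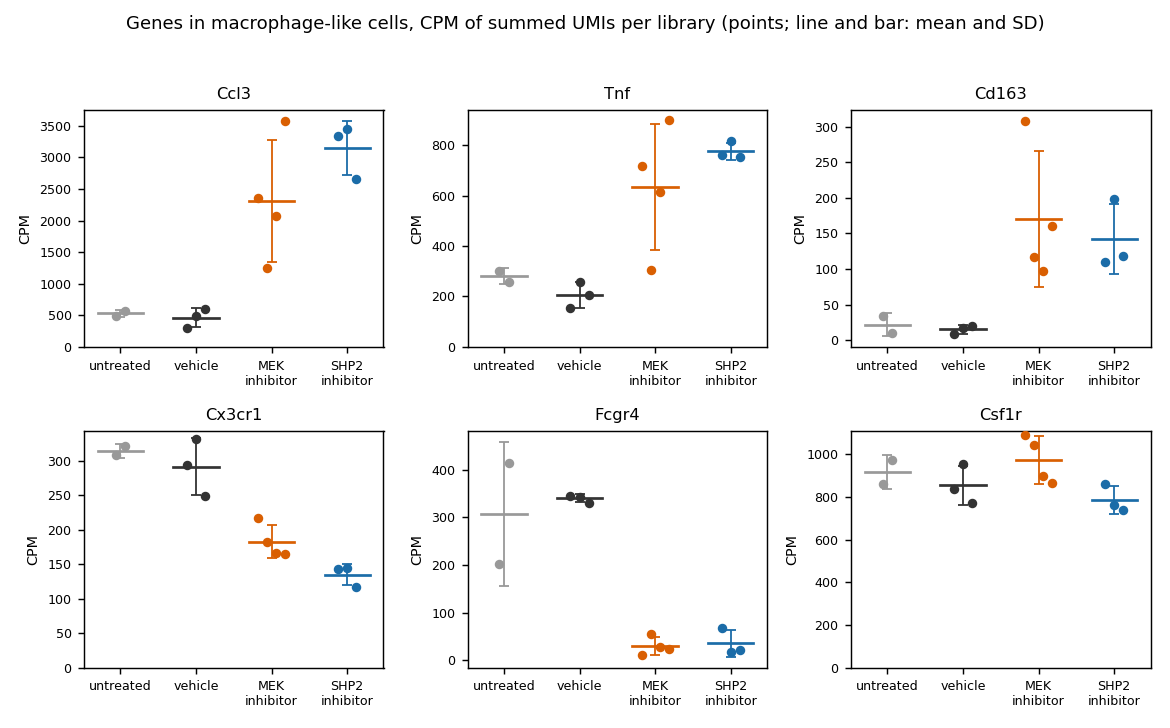
CPM (y axis, linear) of Ccl3, Tnf, Cd163, Cx3cr1, Fcgr4 and Csf1r in macrophage-like cells per library (points) in each group, with a line and bar for the mean and SD. Fcgr4 averaged 340.1 CPM with vehicle, 29.2 with the MEK inhibitor and 35.6 with the SHP2 inhibitor.

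In Schwann-like cells, the lineage that lacks Nf1, the MEK inhibitor was followed by lower matrix genes. Fbln2, which encodes an extracellular matrix fibulin, fell (108 ± 47.1 against 746 ± 50.1 CPM, log2 fold change -2.79 ± 0.26, adjusted p = 7e-05, SD and SE, n = 4 and 3), with the thrombospondin gene Thbs2 (114 ± 44.4 against 651 ± 111 CPM, log2 fold change -2.51 ± 0.27, adjusted p = 0.00019) and the collagen gene Col8a1 (47.1 ± 24.8 against 412 ± 62.8 CPM, log2 fold change -3.13 ± 0.38, adjusted p = 0.00036). Tnfsf11, which encodes the osteoclast cytokine RANKL, rose (38.1 ± 3.94 against 7.24 ± 3.41 CPM, log2 fold change 2.33 ± 0.22, adjusted p = 9.8e-05). Others among the 6 highest were genes of sensory neurons, Avil (2.73 ± 0.55), Scn11a (2.44 ± 0.53) and Scn10a (2.27 ± 0.46). Of neuron markers 5 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 1.80 (adjusted p = 0.0041, adjusted p = 0.5 with an estimated correlation). Of macrophage markers 0 rose and 9 fell (0 and 9 adjusted over the list alone), with a median of -1.76 (adjusted p = 0.00047, adjusted p = 0.5 with an estimated correlation).

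Of 23 measured collagen and matrix genes 1 rose and 17 fell (1 and 19 adjusted over the list alone), including Col12a1 (-2.31 ± 0.26), Tnc (-2.23 ± 0.33) and Col4a2 (-1.53 ± 0.20). The matrix list median was -1.16 (adjusted p = 1.3e-09, adjusted p = 0.5 with an estimated correlation). Within the TGF-beta response 1 of 11 rose and 4 fell (1 and 5 adjusted over the list alone), with Ltbp2 at -5.88 ± 0.57 and Pmepa1 at -1.17 ± 0.14. The TGF-beta list median was -0.55 (adjusted p = 0.014, adjusted p = 0.51 with an estimated correlation). Of MHC class II genes 0 of 6 rose and 4 fell (0 and 4 adjusted over the list alone). Their median was -2.27 (adjusted p = 0.00033, adjusted p = 0.46 with an estimated correlation). In the list of Cx3cr1 and other microglia-associated genes, 0 of 9 rose and 5 fell (0 and 7 adjusted over the list alone). Their median was -1.31 (adjusted p = 0.00033, adjusted p = 0.46 with an estimated correlation). Their fallen members, such as Cd74 and Csf1r, all lay under 30% of the whole-library level in Schwann-like cells. Myelin genes and immature Schwann cell genes were not called (medians -0.08 and 0.10, adjusted p = 0.58 and 0.97), nor was the cell cycle list (median -0.93, adjusted p = 0.73). Leaving out MEK inhibitor library 1 or 2 or vehicle library 3 moved the count of called lists from 4 to 7, 8 and 8.

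In all, 2786 of 13072 genes were called in Schwann-like cells with the MEK inhibitor (1580 up, 1206 down), 2582 of them at 30% or more of the whole-library level. The count was 1244 without vehicle library 1, 1838 without MEK inhibitor library 3, 1675 without MEK inhibitor library 4 and 320 within cluster 4. Cluster 14, led by Postn, Pcdh20 and Thbs2, held 29.0% of the class with vehicle and 1.73% with the MEK inhibitor, while cluster 5, led by Ucn2 and Gfap, held 4.39% and 26.1%. Within cluster 4 the collagen and matrix list had a median of -0.14 and did not pass (adjusted p = 0.16), the TGF-beta list had a median of 0.36 (adjusted p = 0.71) and the Cx3cr1 list one of -0.71 (adjusted p = 0.16).

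With the SHP2 inhibitor Id3, an inhibitor of basic helix-loop-helix factors, rose in Schwann-like cells (453 ± 32.7 against 92.5 ± 9.69 CPM, log2 fold change 2.29 ± 0.17, adjusted p = 3.3e-05, SD and SE, n = 3 and 3), with the stress gene Gadd45g (133 ± 9.91 against 21.1 ± 5.62 CPM, log2 fold change 2.66 ± 0.25, adjusted p = 0.00012) and Tnfsf11 (47.9 ± 2.49 against 7.24 ± 3.41 CPM, log2 fold change 2.66 ± 0.23, adjusted p = 6e-05). Tnc, the matrix protein tenascin, fell (33.3 ± 3.97 against 282 ± 91.7 CPM, log2 fold change -3.08 ± 0.38, adjusted p = 0.00051), with Ajap1 (-3.09 ± 0.27) and Igfbp3 (-2.95 ± 0.32). Of neuron markers 3 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 1.62 (adjusted p = 0.0033, adjusted p = 0.62 with an estimated correlation), and of macrophage markers 0 rose and 8 fell (0 and 9 adjusted over the list alone), with a median of -2.53 (adjusted p = 3.9e-06, adjusted p = 0.49 with an estimated correlation).

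Of collagen and matrix genes 0 of 23 rose and 19 fell (0 and 19 adjusted over the list alone), with Col5a2 at -2.24 ± 0.30. The matrix list median was -1.48 (adjusted p = 3.3e-13, adjusted p = 0.29 with an estimated correlation). For the TGF-beta response, 1 of 11 rose and 6 fell (1 and 7 adjusted over the list alone). Their median was -0.73 (adjusted p = 0.00062, adjusted p = 0.29 with an estimated correlation). Among interferon response genes 7 of 18 rose and 1 fell (7 and 1 adjusted over the list alone), with Ifi47 at 2.02 ± 0.20, Irgm1 at 1.82 ± 0.25 and Gbp2 at 1.81 ± 0.23. The interferon list median was 0.29 (adjusted p = 0.0084, adjusted p = 0.48 with an estimated correlation). Of immediate early genes 6 of 18 rose and 0 fell (6 and 1 adjusted over the list alone), with Socs3 at 1.34 ± 0.19 and Junb at 0.87 ± 0.15. The immediate early list median was 0.20 (adjusted p = 0.038, adjusted p = 0.48 with an estimated correlation). Of glycolysis and hypoxia genes 5 of 16 rose and 0 fell (5 and 0 adjusted over the list alone), with Bnip3 at 0.89 ± 0.18. The glycolysis list median was 0.22 (adjusted p = 0.01, adjusted p = 0.29 with an estimated correlation). Of p53 and apoptosis genes 1 of 12 rose and 4 fell (2 and 4 adjusted over the list alone), the death receptor gene Fas rising (1.38 ± 0.19) and Bax falling (-0.81 ± 0.12). The p53 list median was -0.61 (adjusted p = 0.038, adjusted p = 0.48 with an estimated correlation). Of MHC class II genes 0 of 6 rose and 4 fell (0 and 4 adjusted over the list alone). Their median was -2.64 (adjusted p = 0.00062, adjusted p = 0.29 with an estimated correlation). Of Cx3cr1 and microglia-associated genes 0 of 9 rose and 6 fell (0 and 8 adjusted over the list alone). Their median was -1.78 (adjusted p = 1.9e-05, adjusted p = 0.29 with an estimated correlation). For inflammatory genes, 0 of 16 rose and 4 fell (0 and 4 adjusted over the list alone). Their median was -0.75 (adjusted p = 0.0026, adjusted p = 0.48 with an estimated correlation). For monocyte genes, 0 of 4 rose and 1 fell (0 and 2 adjusted over the list alone). Their median was -0.65 (adjusted p = 0.01, adjusted p = 0.29 with an estimated correlation).

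In Schwann-like cells 2163 genes were called with the SHP2 inhibitor (1092 up, 1071 down), 1959 of them at 30% or more of the whole-library level. The count was 894 without vehicle library 1, 1280, 1041 and 1200 without SHP2 inhibitor library 1, 2 and 3, and 67 within cluster 4. Cluster 14 held 0.242% of the class with the SHP2 inhibitor and cluster 5 held 26%. Within cluster 4 the collagen and matrix list had a median of -0.40 with 1 member down (adjusted p = 0.0064, adjusted p = 0.9 with an estimated correlation). The inflammatory, p53, TGF-beta and interferon lists had medians of 0.0094, 0.063, -0.18 and 0.22 there and did not pass (adjusted p = 0.44, 0.83, 0.95 and 0.28), nor did the monocyte and glycolysis lists (adjusted p = 0.28 and 0.2).

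In fibroblast-like cells the MEK inhibitor was again followed by lower matrix genes. The basement membrane collagens Col4a1 (298 ± 50.8 against 727 ± 65 CPM, log2 fold change -1.29 ± 0.14, adjusted p = 0.00017, SD and SE, n = 4 and 3) and Col4a2 (156 ± 17.2 against 494 ± 24.6 CPM, log2 fold change -1.66 ± 0.13, adjusted p = 7e-05) fell, and so did the matrix gene Postn (17 ± 11 against 196 ± 74.7 CPM, log2 fold change -3.52 ± 0.47, adjusted p = 0.00063). Kng2, which encodes a kininogen (3.39 ± 2.84 against 66.5 ± 9.35 CPM, log2 fold change -4.19 ± 0.46, adjusted p = 0.00018) and Cxcl14 (-3.01 ± 0.32) were among the lowest. The highest held Dpep1 (174 ± 183 against 25.6 ± 9.13 CPM, log2 fold change 2.78 ± 0.60, adjusted p = 0.0074) and the metallothionein gene Mt2 (2.34 ± 0.34, adjusted p = 0.0011). The chemokine genes Ccl2 (1.50 ± 0.31, adjusted p = 0.0063) and Cxcl12 (236 ± 115 against 69.2 ± 3.3 CPM, log2 fold change 1.77 ± 0.29, adjusted p = 0.0019) rose. Csf1, the macrophage growth factor, rose (0.93 ± 0.23, adjusted p = 0.014), and was not called without vehicle library 2 (0.79).

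Among collagen and matrix genes 0 of 23 rose and 13 fell (0 and 15 adjusted over the list alone), with Col3a1 at -1.21 ± 0.20. The matrix list median was -0.96 (adjusted p = 1.7e-06, adjusted p = 0.37 with an estimated correlation). Of macrophage-attracting ligands 4 of 8 rose and 0 fell (4 and 0 adjusted over the list alone), with Ccl7 at 1.46 ± 0.29. The attractant list median was 0.95 (adjusted p = 0.034, adjusted p = 0.37 with an estimated correlation). Of receptor tyrosine kinases 4 of 14 rose and 0 fell (5 and 0 adjusted over the list alone), with Fgfr2 at 0.99 ± 0.21. The receptor list median was 0.27 (adjusted p = 0.034, adjusted p = 0.37 with an estimated correlation). Of TGF-beta response genes 1 of 11 rose and 4 fell (1 and 4 adjusted over the list alone), with Pmepa1 at -1.84 ± 0.18 and Tgfb1 at -0.95 ± 0.15. The TGF-beta list median was -0.43 (adjusted p = 0.028, adjusted p = 0.37 with an estimated correlation). Of p53 and apoptosis genes 1 of 12 rose and 5 fell (1 and 8 adjusted over the list alone), with Mdm2, whose product degrades p53, at -1.36 ± 0.21. The p53 list median was -0.70 (adjusted p = 0.0063, adjusted p = 0.37 with an estimated correlation). Of immediate early genes 2 of 18 rose and 0 fell (2 and 0 adjusted over the list alone). Their median was 0.35 (adjusted p = 0.049, adjusted p = 0.49 with an estimated correlation). Of MHC class II genes 0 of 6 rose and 5 fell (0 and 5 adjusted over the list alone). Their median was -2.15 (adjusted p = 9.8e-05, adjusted p = 0.37 with an estimated correlation). Of myelin genes 9 of 15 rose and 1 fell (10 and 1 adjusted over the list alone). Their median was 1.31 (adjusted p = 0.00059, adjusted p = 0.37 with an estimated correlation). Of immature Schwann cell genes 7 of 12 rose and 0 fell (7 and 1 adjusted over the list alone). Their median was 1.07 (adjusted p = 0.02, adjusted p = 0.37 with an estimated correlation). Among Schwann cell markers 9 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 1.02 (adjusted p = 1.7e-05). Among neuron markers 6 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 2.00 (adjusted p = 0.00046). Among satellite glial markers 4 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 2.20 (adjusted p = 0.00074). Among macrophage markers 0 rose and 8 fell (0 and 9 adjusted over the list alone), with a median of -1.37 (adjusted p = 0.00073). With an estimated correlation adjusted p was 0.22 or more for these markers.

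The MEK inhibitor changed 2732 of 13056 genes in fibroblast-like cells (1196 of them down), 2160 at 30% or more of the whole-library level. The count was 1367 without vehicle library 2 and 71 within cluster 10. Cluster 9, led by Cst6, Fbn2 and Inhba, held 77.7% of the class with vehicle and 13.5% with the MEK inhibitor, while cluster 10, led by Myoc, Crispld2 and Dpep1, held 22.3% and 86.5%. Within cluster 10 the collagen and matrix list had a median of -0.07 and did not pass (adjusted p = 0.31), and immediate early genes had a median of -0.43 (adjusted p = 0.054). The attractant (median 0.092), receptor (0.033), TGF-beta (-0.26), p53 (-0.18) and immature Schwann cell lists (0.82) lost their calls there (adjusted p of 0.065 or more). Ccl2 is among the genes that mark the cluster. Within cluster 9, where 3 of the 4 MEK inhibitor libraries had enough cells, 91 genes were called. There the matrix list had a median of -0.29 with 2 members down (adjusted p = 0.019, adjusted p = 0.54 with an estimated correlation), and the attractant list one of -0.17 (adjusted p = 0.36).

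In fibroblast-like cells given the SHP2 inhibitor Col4a1 (223 ± 11.5 against 727 ± 65 CPM, log2 fold change -1.70 ± 0.15, adjusted p = 0.00013, SD and SE, n = 3 and 3) and Col4a2 (-1.91 ± 0.15) fell, with Postn (-3.65 ± 0.54). Igfbp5 fell (136 ± 23 against 1801 ± 1134 CPM, log2 fold change -3.73 ± 0.56, adjusted p = 0.0015), as did Kng2 (-3.56 ± 0.50) and F2rl1 (-4.30 ± 0.60). Stat2, which carries type I interferon signals, rose (35.9 ± 5.91 against 13.5 ± 2.03 CPM, log2 fold change 1.41 ± 0.16, adjusted p = 0.00037). The highest genes, such as Pirt, Tusc5 and Fxyd2, are genes of sensory neurons and lay at 0.13 to 0.32 times their whole-library level in fibroblast-like cells. Ccl2 (1.21 ± 0.32, adjusted p = 0.02) was not called without vehicle library 1 (1.16), vehicle library 2 (1.17) or SHP2 inhibitor library 2 (0.74).

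Of collagen and matrix genes 0 of 23 rose and 18 fell (0 and 19 adjusted over the list alone). Their median was -1.47 (adjusted p = 3.1e-11, adjusted p = 0.34 with an estimated correlation). Of interferon response genes 6 of 20 rose and 2 fell (10 and 2 adjusted over the list alone), with Irgm1 at 1.64 ± 0.22 and Gbp2 at 1.62 ± 0.29. The interferon list median was 0.57 (adjusted p = 0.04, adjusted p = 0.56 with an estimated correlation). Of TGF-beta response genes 0 of 11 rose and 3 fell (0 and 4 adjusted over the list alone). Their median was -0.47 (adjusted p = 0.04, adjusted p = 0.34 with an estimated correlation). Among p53 and apoptosis genes 1 of 12 rose and 3 fell (1 and 4 adjusted over the list alone). Their median was -0.39 (adjusted p = 0.04, adjusted p = 0.56 with an estimated correlation). Of MHC class II genes 0 of 6 rose and 5 fell (0 and 5 adjusted over the list alone). The MHC class II list median was -2.22 (adjusted p = 0.00022, adjusted p = 0.34 with an estimated correlation). Of myelin genes 9 of 15 rose and 0 fell (10 and 0 adjusted over the list alone). Their median was 1.51 (adjusted p = 5.5e-05, adjusted p = 0.34 with an estimated correlation). Of immature Schwann cell genes 7 of 12 rose and 0 fell (7 and 0 adjusted over the list alone). Their median was 0.97 (adjusted p = 0.0033, adjusted p = 0.34 with an estimated correlation). Among Schwann cell markers 12 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 1.47 (adjusted p = 6.5e-07, adjusted p = 0.17 with an estimated correlation). Among neuron markers 7 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 2.12 (adjusted p = 0.00013, adjusted p = 0.49 with an estimated correlation). Among satellite glial markers 4 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 2.36 (adjusted p = 0.00055, adjusted p = 0.17 with an estimated correlation). Among macrophage markers 0 rose and 8 fell (0 and 10 adjusted over the list alone), with a median of -1.99 (adjusted p = 2.6e-05, adjusted p = 0.39 with an estimated correlation).

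The SHP2 inhibitor changed 2535 genes in fibroblast-like cells (1374 up, 1161 down), 1937 of them at 30% or more of the whole-library level. The count was 1311 without vehicle library 2, 1503, 1599 and 1498 without SHP2 inhibitor library 1, 2 and 3, and 117 within cluster 10, which held 89.9% of the class against 10.1% in cluster 9. Within cluster 10 the collagen and matrix list was lower (median -0.73, 6 members down, adjusted p = 1.9e-08, adjusted p = 0.2 with an estimated correlation). The interferon, TGF-beta and p53 lists had medians of -0.11, -0.33 and -0.056 there and did not pass (adjusted p = 0.65, 0.31 and 0.77). Within cluster 9, with 25 genes called, the matrix list was lower (median -0.36, 2 members down, adjusted p = 0.0085). The interferon (0.62, adjusted p = 0.023) and TGF-beta lists (-0.90, adjusted p = 0.021) kept their calls there, unlike p53 (adjusted p = 0.22). Adjusted p was 0.36 or more with an estimated correlation.

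**Figure D3:**
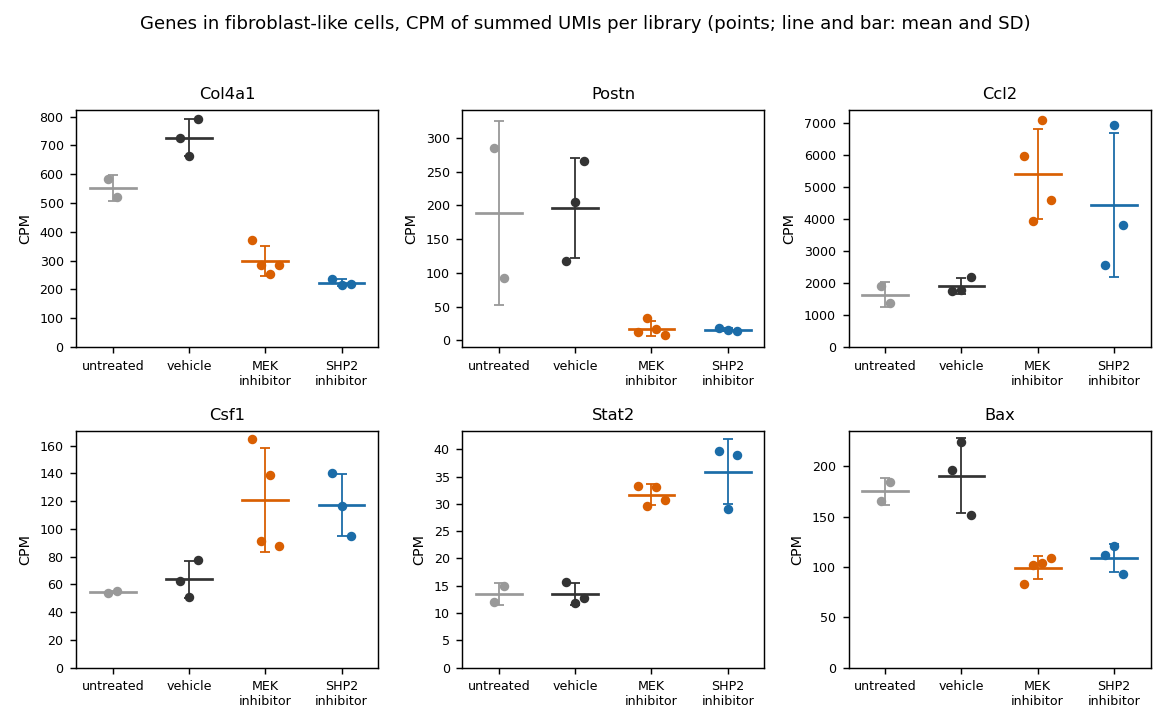
CPM (y axis, linear) of Col4a1, Postn, Ccl2, Csf1, Stat2 and Bax in fibroblast-like cells per library (points) in each group, with a line and bar for the mean and SD. Col4a1 averaged 727 CPM with vehicle, 298 with the MEK inhibitor and 223 with the SHP2 inhibitor.

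Since both drugs act on the RAS pathway, the transcripts that ERK induces were read as a list fixed before the data were examined. The list was called in none of the drug-vehicle comparisons of these 3 classes (medians 0.29 and 0.41 in macrophage-like, 0.29 and 0.11 in Schwann-like, and 0.19 and 0.27 in fibroblast-like cells; adjusted p from 0.26 to 0.93). Its members went both ways: in Schwann-like cells 5 of 18 rose and 3 fell (6 and 3 adjusted over the list alone) with the MEK inhibitor and 4 of 18 rose and 3 fell (5 and 3 adjusted over the list alone) with the SHP2 inhibitor. Ccnd1, which encodes cyclin D1 and, like the next genes, was chosen after its values were seen, fell in all 3 classes. In fibroblast-like cells it went from 373 ± 23.6 CPM to 116 ± 26 with the MEK inhibitor (-1.69 ± 0.25, adjusted p = 0.0011) and 90 ± 23.2 with the SHP2 inhibitor (-2.05 ± 0.27, adjusted p = 0.00095). In Schwann-like cells its log2 fold changes were -1.62 ± 0.25 and -1.97 ± 0.28, and in macrophage-like cells -2.22 ± 0.43 and -2.45 ± 0.50. Etv4, an ERK-induced transcription factor gene, fell in fibroblast-like cells (-1.38 ± 0.16 and -2.01 ± 0.19). Phlda1 rose in Schwann-like cells (1.28 ± 0.15 and 1.35 ± 0.15), as did Spred1 in macrophage-like cells (1.24 ± 0.18 and 1.41 ± 0.19). Dusp6, a phosphatase that ERK induces, did not pass in macrophage-like cells (-0.64 ± 0.48, adjusted p = 0.39), and passed without MEK inhibitor library 1 (-1.56). In fibroblast-like cells it had 0.98 ± 0.40 (adjusted p = 0.095) with the MEK inhibitor, and passed by DESeq2 (0.99) and without MEK inhibitor library 3 (1.21). The Cx3cr1 and microglia-associated list was not called in macrophage-like cells against vehicle (medians 0.08 and -0.09, adjusted p = 0.54 and 0.24), though it was within cluster 15 with the SHP2 inhibitor. Oxidative phosphorylation genes were called in no comparison of the 3 whole classes, and were higher within fibroblast cluster 10 (medians 0.21 and 0.24, adjusted p = 0.0099 and 0.0032) and, with the SHP2 inhibitor, macrophage cluster 15 (0.29, adjusted p = 0.018; adjusted p of 0.54 or more with an estimated correlation).

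**Figure D4:**
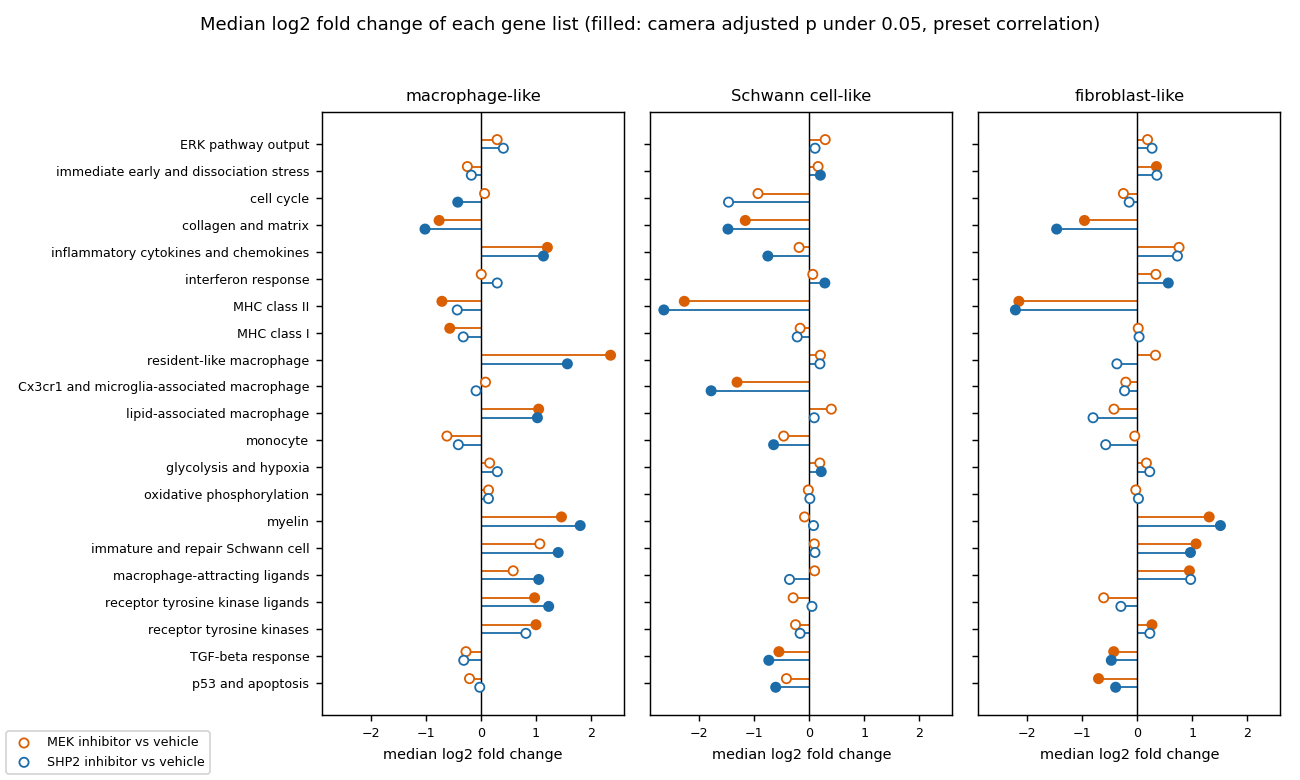
Median log2 fold change (x axis) of each pathway list (y axis) in the 3 classes for each drug against vehicle, filled where camera's adjusted p with the preset correlation is under 0.05. The collagen and matrix list lies below 0 in all 6 comparisons, from -1.48 to -0.76.

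Whether both drugs moved the same genes was asked by overlap. In macrophage-like cells 531 genes rose and 341 fell with both drugs, against 65.5 and 33.0 for independent lists, and 0 moved in opposite directions. Schwann-like cells shared 963 and 866 (132 and 98.8 for independent lists) and fibroblast-like cells 1067 and 792 (162 and 106), with 0 opposite. Log2 fold changes of the 2 drugs correlated across genes, which are not independent replicates, at r = 0.84, 0.92 and 0.89 (covariance 0.48, 0.49 and 0.62). Simulated unchanged groups sharing vehicle libraries gave r = 0.43, 0.59 and 0.50 (covariance 0.051, 0.058 and 0.056). With no shared control (MEK inhibitor against untreated, SHP2 inhibitor against vehicle), r was 0.74, 0.75 and 0.81 (covariance 0.54, 0.57 and 0.72, simulated r from -0.027 to -0.0063). Cluster shifts common to both drugs were not simulated.

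The 2 drugs were then compared with each other. No gene passed edgeR's test in macrophage-like, Schwann-like or fibroblast-like cells (0 each, with 525, 451 and 851 genes at an unadjusted p under 0.05, and 2, 1 and 34 called by DESeq2). Without MEK inhibitor library 3 edgeR called 2 genes in Schwann-like and 3 in fibroblast-like cells. The collagen and matrix list was lower with the SHP2 than with the MEK inhibitor in fibroblast-like cells (median -0.33, adjusted p = 2.5e-06, adjusted p = 0.69 with an estimated correlation). It was lower in Schwann-like cells as well (median -0.30, adjusted p = 0.0016, adjusted p = 0.68 with an estimated correlation). Adjusted over the list alone, 3 members fell in fibroblast-like and 1 in Schwann-like cells. Interferon genes were higher in fibroblast-like cells (median 0.34, adjusted p = 0.0043, adjusted p = 0.69 with an estimated correlation) and in Schwann-like cells (median 0.20, adjusted p = 0.023, adjusted p = 0.68 with an estimated correlation). In macrophage-like cells they were higher too (median 0.40, adjusted p = 0.029, adjusted p = 0.61 with an estimated correlation). The Cx3cr1 list was lower in macrophage-like cells (median -0.37, adjusted p = 0.00048, adjusted p = 0.41 with an estimated correlation), with 5 members down adjusted over the list alone. There the resident-like list (median -0.72, adjusted p = 0.0014, adjusted p = 0.61 with an estimated correlation) and the cell cycle list (median -0.65, adjusted p = 0.0042, adjusted p = 0.41 with an estimated correlation) were lower. Inflammatory genes were higher in macrophage-like cells (median 0.21, adjusted p = 0.029, adjusted p = 0.61 with an estimated correlation). They were lower in Schwann-like cells (median -0.53, adjusted p = 1.5e-05, adjusted p = 0.6 with an estimated correlation). In fibroblast-like cells the resident-like list was lower (median -0.32, adjusted p = 0.015, adjusted p = 0.29 with an estimated correlation).

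Between the drugs 8 lists were called in macrophage-like cells (5 without MEK inhibitor library 2, 4 without library 3, 5 without SHP2 inhibitor library 2 and 3 without library 3). In Schwann-like cells 7 were called (4 without MEK inhibitor library 1, 2 without library 2, and 3, 4 and 4 without SHP2 inhibitor library 1, 2 and 3), and in fibroblast-like cells 3 (6 without SHP2 inhibitor library 2). The Cx3cr1 and myelin lists in Schwann-like cells turned direction within cluster 4 (medians 0.034 and -0.0085). Calls lost within 1 cluster were those of the cell cycle, inflammatory, lipid-associated and myelin lists in macrophage-like cells, the ERK output, interferon, Cx3cr1 and myelin lists in Schwann-like cells and the resident-like list in fibroblast-like cells (adjusted p of 0.058 or more). Of called lists in the macrophage comparison, MHC class I, lipid-associated and myelin genes had medians of 0.24, 0.16 and 0.35 (each with adjusted p = 0.029, adjusted p = 0.61 with an estimated correlation). In Schwann-like cells ERK output, cell cycle, Cx3cr1 list and myelin genes had medians of -0.10, -0.65, -0.41 and 0.17 (adjusted p = 0.0498, 0.023, 0.015 and 0.015, and adjusted p of 0.60 or more with an estimated correlation).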

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

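The tests in this part were applied to results already computed, and the genes Ccnd1 and Igf1 in macrophage-like cells were chosen after their values were seen. Only the MEK inhibitor group has the 4 libraries that the test of a single distant library needs. It was run on 183 sets of 4 values and marked 22, where chance marks about 1 in 20 sets, and sets from 1 library are not independent. Of these, 18 were MEK inhibitor library 1 and 4 were MEK inhibitor library 2.

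MEK inhibitor library 1 alone in its group came from a female (Xist at 1211 CPM, against 0.154 to 14.4) and had barcodes of 500 UMIs. More of its cells were stromal or immune than in the other 3. Fewer were neuron-like (4.44%, against 20.4 to 33.7%) or satellite glial-like (1.80%, against 4.33 to 5.83%), though neither was marked. Fibroblast-like cells were 26.6% of its cells (9.53 to 12% in the others), perineurial-like cells 5.21% (1.60 to 2.01%), mural-like cells 4.95% (0.916 to 1.48%), macrophage-like cells 9.32% (3.61 to 4.34%), T-like cells 0.514% (0.113 to 0.166%) and mast-like cells 0.374% (0.106 to 0.143%). Among cells with at least 2000 UMIs the macrophage-like percent was 9.69 (5.31 to 5.68).

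In its macrophage-like cells Cbr2 was at 449.9 CPM (106 to 137 in the other 3), the eotaxin gene Ccl24 at 146 CPM (23.4 to 29.1), Ccnd1 at 49.5 CPM (14.3 to 16.1), the growth factor gene Igf1 at 172 CPM (90.3 to 104) and Ptpn11 at 28.9 CPM (40.2 to 42.5). In its Schwann-like cells Irgm1 was at 224 CPM (142 to 155), Slc10a6 at 80.7 CPM (41.3 to 47.6), the glucose transporter gene Slc2a1 at 52.1 CPM (48.4 to 48.9) and the sodium channel gene Scn11a at 16.2 CPM (53 to 57). In its fibroblast-like cells Dpep1 was at 448 CPM (69.8 to 94.9) and Mt2 at 3861 CPM (1496 to 1600). In MEK inhibitor library 2 Gpnmb was at 70.3 CPM in macrophage-like cells (11.9 to 18.8), Bax at 79.5 CPM (61.6 to 64.6) and Fbln2 at 178 CPM (78.4 to 89.0) in Schwann-like cells, and the glutamate receptor gene Gria1 at 12.8 CPM in fibroblast-like cells (3.78 to 5.22). No explanation of these values was tested.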

How the results depend on the processing

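The alternatives run within 1 cluster or within cluster 9, with sex as a covariate, at 30% or more of the whole-library level, without low-UMI clusters and with another denominator were chosen after the data were seen. Single genes were run under DESeq2, RLE size factors, 2 groups only, pooled controls and a library left out. Of 241 such results, 196 kept direction and call under each of these and 0 turned direction. DESeq2 left 240 of 241 alike and 1 stronger, RLE size factors all 241, and leaving out 1 library left 1446 of 1564 alike, 115 weaker and 3 stronger. For genes called, sex as a covariate, RLE size factors, doublets kept, the stricter cell filter, the 30% level, low-UMI clusters left out and only 2 groups in the fit kept each of the 12 counts within 1.5 times. With separate controls both drugs raised 397, 846 and 932 genes and lowered 254, 740 and 631 in macrophage-like, Schwann-like and fibroblast-like cells, each sum within 1.5 times of that with shared controls. Depth limits untreated library 1 most in Schwann-like and fibroblast-like sums and a drug library most in macrophage-like sums, and for macrophage-like and fibroblast-like cells with the SHP2 inhibitor the simulation missed more of the 2-fold changes than it found. No paired analysis was possible because the labels number samples within groups only and tie no sample to one of another group. Unless stated, the cause was not tested.

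Counts of genes that moved over 1.5 times follow. With untreated and vehicle pooled, Schwann-like cells had 4212 (MEK inhibitor) and 3543 (SHP2 inhibitor) genes called, a fit with more control libraries. Thinned to equal totals they had 1853 and 1441, and macrophage-like cells with the MEK inhibitor 938, from fewer UMIs. Within 1 cluster, with fewer cells, the counts were 320 and 67 in Schwann-like, 71 and 117 in fibroblast-like (91 and 25 in cluster 9, and 1 between the drugs) and 87 and 88 in macrophage-like cells. DESeq2 called 1, 34 and 2 genes between the drugs in Schwann-like, fibroblast-like and macrophage-like cells, and 1 and 5 between vehicle and untreated in Schwann-like and fibroblast-like cells. With no low-count filter there were 1 (Schwann-like), 1 (fibroblast-like) and 134 (macrophage-like) genes between vehicle and untreated, 5 (fibroblast-like) and 77 (macrophage-like) between the drugs, and 1951 in macrophage-like cells with the SHP2 inhibitor. The cause was not tested.

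With 1 library left out, genes called with the MEK inhibitor ran from 1244 to 3218 in Schwann-like, 1367 to 2713 in fibroblast-like and 506 to 1829 in macrophage-like cells. For the SHP2 inhibitor they ran from 894 to 2289, 1311 to 2136 and 435 to 1422. Between the drugs the ranges were 0 to 2 in Schwann-like and 0 to 3 in fibroblast-like cells, and for vehicle against untreated 0 to 1 in macrophage-like cells. Lists called ran from 3 to 8 in Schwann-like cells with the MEK inhibitor, and between the drugs from 2 to 9 in Schwann-like, 2 to 6 in fibroblast-like and 3 to 8 in macrophage-like cells.

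The number of lists called was 0 with an estimated correlation in each of the 12 comparisons, and 66 of 66 called lists were weaker. By fry, 40 of the 66 kept their call, 11 lists were called in Schwann-like cells with the MEK inhibitor, 0, 1 and 0 between the drugs in Schwann-like, fibroblast-like and macrophage-like cells, and 0 in each class between vehicle and untreated. With pooled controls Schwann-like cells had 7 with the MEK inhibitor. Within 1 cluster there were 1 and 5 in Schwann-like cells (MEK and SHP2 inhibitor), 4 in fibroblast-like cells with the MEK inhibitor and 4 in macrophage-like cells between the drugs. Medians of 9 lists turned direction within 1 cluster. In Schwann-like cells these were TGF-beta with the MEK inhibitor (0.36), inflammatory (0.0094) and p53 genes (0.063) with the SHP2 inhibitor, and the Cx3cr1 list (0.034) and myelin (-0.0085) between the drugs. In fibroblast-like cells they were immediate early genes with the MEK inhibitor (-0.43) and interferon genes with the SHP2 inhibitor (-0.11). In macrophage-like cells they were MHC class II with the MEK inhibitor (1.26) and resident-like genes with the SHP2 inhibitor (-0.22). Within cluster 9 of fibroblast-like cells attractant genes with the MEK inhibitor turned (-0.17). The cause was not tested.

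Shares passed the test more often when edgeR was run on cell counts, with log2 fold changes of 1.37 (Schwann-like) and -2.62 (macrophage-like) for the MEK inhibitor and -3.02 (macrophage-like) for the SHP2 inhibitor against vehicle. Against drug-free libraries both shares with the SHP2 inhibitor passed (adjusted p = 0.0417) with doublets kept (18.4 and -25.2 percentage points), the stricter filter (25.1 and -27.4), low-UMI clusters left out (29.7 and -27.8) and the other denominator (31.7 and -31.2), and by edgeR (log2 1.10 and -2.88). With 1 library left out, the MEK inhibitor against drug-free ran from 21.0 to 24.8 points for Schwann-like and from -26.8 to -20.8 for macrophage-like cells, with fewer splits and so larger p-values.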

Other observations

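The gene tests in endothelial-like cells (and in perineurial-like and dendritic-like cells, not described here), the counts of genes with opposite directions in 2 classes, and the bounds used to weigh the 3 patterns were chosen after results were seen. In endothelial-like cells, which line vessels, Sox4 fell from 828 ± 152 CPM with vehicle (SD, n = 3) to 106 ± 24.0 with the MEK inhibitor (n = 4, log2 fold change -2.96 ± 0.22, edgeR adjusted p = 1.4e-06) and 91.5 ± 26 with the SHP2 inhibitor (n = 3, -3.16 ± 0.24, adjusted p = 4e-06). The receptor gene Kit went from 96.2 ± 44.1 to 2.62 ± 1.79 and 4.62 ± 3.40 CPM, the integrin gene Itgb3 from 112 ± 28.6 to 13.3 ± 3.53 and 15.2 ± 3.38 CPM, and the laminin gene Lamb1 from 173 ± 52.1 to 15.7 ± 3.73 and 27.7 ± 5.74 CPM, with each adjusted p under 0.05. The interferon-induced genes Irgm1 (1.45 ± 0.16 and 1.33 ± 0.16) and Ifi47 (1.42 ± 0.15 and 1.26 ± 0.15) rose. Of 19 measured interferon response genes 12 rose and 0 fell with the MEK inhibitor (median 1.11, adjusted p = 2e-09, adjusted p = 0.13 with an estimated correlation), and 8 rose and 0 fell with the SHP2 inhibitor (median 0.83, adjusted p = 3e-07, adjusted p = 0.15 with an estimated correlation). Genes of ERK output were higher in these cells: of 17 measured, 6 and 8 rose and 0 fell (medians 0.56 and 0.73, adjusted p = 0.00062 and 6.7e-06, adjusted p = 0.13 and 0.12 with an estimated correlation). In all, edgeR called 929 and 879 of 9427 genes against vehicle and 0 between the drugs (461 at an unadjusted p under 0.05; DESeq2 was not run in this class).

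Some genes moved in opposite ways in macrophage-like and fibroblast-like cells: 91 of 471 genes called in both with the MEK inhibitor and 69 of 363 with the SHP2 inhibitor, 41 and 42 of them at 30% or more of the whole-library level and a mean CPM of at least 20 in both. Among those that rose in macrophage-like and fell in fibroblast-like cells were the growth factor gene Igf1 (1.44 ± 0.23 and -1.44 ± 0.21 with the MEK inhibitor, 1.74 ± 0.25 and -1.64 ± 0.23 with the SHP2 inhibitor) and the galectin gene Lgals3 (1.94 ± 0.41 and -1.58 ± 0.37, then 2.07 ± 0.42 and -1.88 ± 0.41). The difference between the classes was not tested.

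The first pattern is the lower macrophage-like share with both drugs. Dilution of the libraries by neuron-like and other barcodes as the whole cause was argued against, since macrophage-like cells per 100 fibroblast-like cells were at 19.7% of the drug-free mean with the MEK inhibitor (exact p = 0.0159) and 15.5% with the SHP2 inhibitor (exact p = 0.0179). Fewer UMIs per cell were argued against too: among cells with at least 2000 UMIs the macrophage-like share was at 20.5% and 17.0% of the drug-free mean (exact p = 0.00794 and 0.0179). More ganglion tissue in the treated samples stays open as an explanation, with mean neuron-like shares of 20.1% and 28.9%. Those were mostly low-UMI barcodes, and without low-UMI clusters the shares lay above the drug-free mean by 1.26 and 1.17 percentage points (adjusted p = 0.019 and 0.042). The explanation cannot be told apart from the SHP2 inhibitor, whose libraries all held more neuron-like cells than any drug-free library. MEK inhibitor library 1 goes against it as the whole cause, with 4.44% neuron-like cells and 35.1 macrophage-like per 100 fibroblast-like cells, beside 10.2% and 219 in vehicle library 3, but a single library does not settle it. A loss of macrophages under the drugs is a further hypothesis. Barcode selection was not tested.

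The second pattern is the lower collagen and matrix list in fibroblast-like cells. With the MEK and SHP2 inhibitors, 13 of 13 and 18 of 18 fallen members lay at 30% or more of their whole-library level. This leaves dilution by RNA of other cells untested. Unequal totals do not account for the pattern, since 14 and 18 members fell in thinned sums. Depth per cell was not tested. A shift from cluster 9 to cluster 10 could carry the change with the MEK inhibitor, where the list's median was -0.0679 within cluster 10 and -0.286 within cluster 9, and the 2 cannot be told apart, because only 1 and 2 members fell there. Given the SHP2 inhibitor, medians were -0.734 (6 members down) in cluster 10 and -0.355 in cluster 9. Clusters were cut from the same expression data, so such a shift stays open beside a lower matrix program in fibroblasts.

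The third pattern is the rise of Schwann cell and neuron genes and the fall of macrophage genes in fibroblast-like cells. Doublets with macrophages stay open for the latter. Cells were thinned to 5000 UMIs (4 to 38 shallower ones left out per vehicle library, 27 to 165 per drug library). A macrophage-marker UMI was in 21.4 to 40.0% of fibroblast-like cells with vehicle, 14.1 and 30.7% untreated, and 9.78 to 15.1% with the drugs. Vehicle library 3, the lowest, lay 6.25 points above the highest drug library. Doublets removed were 3.42% of it and up to 7.71% of a library, and those left in were not counted. Without thinning to match depth, the top 10% of cells held 38.2 to 53.2% of these UMIs with vehicle and 51.2 to 80.4% with drugs. Values are consistent with free RNA of the whole library, as 96.7% of changed genes under 30% of their whole-library level moved as the whole library did with the MEK inhibitor and 98.8% with the SHP2 inhibitor, against 85.5% and 83.1% of other changed genes. A change in the fibroblasts themselves was not tested.

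Other splits of the same libraries were counted. With the MEK inhibitor against vehicle, 1 of 35 splits, the real one, gave as many genes in each class. It gave 1529, 2786 and 2732 in macrophage-like, Schwann-like and fibroblast-like cells (highest others 727, 1631 and 969). This lowest possible share argues against chance without excluding it. For the SHP2 inhibitor the 10 splits are too few for a share under 0.05 (1268, 2163 and 2535 genes, with 0 as the highest of the others in each class). Between the drugs the real count was 0, which each of the 35 splits reaches (highest other 0, 3 and 6), so the splits say nothing there.

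For lists with the MEK inhibitor, 1 of 35 splits gave as many as the real 9 in fibroblast-like cells (highest other 8). That share does not exclude chance, and 0 of the 9 hold with an estimated correlation. Chance cannot be excluded in macrophage-like (5 of 35, real 9, highest other 12) or Schwann-like cells (28 of 35, real 4, highest other 12). For the SHP2 inhibitor the splits are too few again (real 9, 10 and 7, with 7 the highest other in each class, and 1, 1 and 2 of 10 splits as large). Between the drugs chance cannot be excluded for lists: 5, 4 and 20 of 35 splits gave as many as the real 8, 7 and 3 (highest other 9, 10 and 7).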
